A study of Scophthalmus maximus with 25 samples.

How the data were processed

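Gene expression was measured in livers of juvenile turbot (Scophthalmus maximus), a marine flatfish, with 25 one-colour Agilent oligonucleotide arrays. Fish were kept in seawater with dissolved styrene, a volatile aromatic hydrocarbon shipped in bulk as a plastics monomer, or in clean seawater, and livers were taken after 3 or 7 days. Groups were read from the labels: 7 control and 6 styrene-exposed fish at day 3, and 6 and 6 at day 7. Per the labels' protocols, the fish weighed 358 ± 93 g (SD) and measured 28 ± 2 cm (SD), and were acclimatized for 20 days. Control and exposed fish lived in separate tanks, and the labels describe 1 exposure tank of 300 L fed from a mixing tank of 316 L, so tank and treatment cannot be told apart. The labels used here give no styrene concentration. They mention 1 sample that was labelled again as a control without tying it to arrays. Titles of 6 of the 7 day 3 controls, and of no other group, carry a suffix that could mark a repeat of the sample or the array, which the labels do not explain. Each array was taken as a separate fish, and a repeat confined to this group would enter the day 3 and between-day comparisons. Total RNA was extracted with Trizol and a column kit, and 200 ng was labelled with Cy3 by in vitro transcription, per the labels' protocols.

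Per the file headers, the scanner images were read with Agilent Feature Extraction 9.5.3.1, which the submitters' processing notes also name without a version. The deposited scanner files give, per spot, a raw mean intensity, a local background intensity and a processed signal. The processed signal had been background-subtracted and detrended across the array by the software, with surrogate values in place of signals near background, per the file headers, and it had not been scaled between arrays. Each array held 13580 spots of 2716 probes, 5 spots per probe, besides control spots. The deposited series table holds the authors' processed signal for 2392 probes in each of its 25 columns. Set against the scanner files, the table was linear and ran in the same direction, with correlations of at least 0.996 on the log2 scale. It was not centred per probe, and the scale factor of each column, and how the authors chose it, stayed unknown. Column medians for replicates 1 to 7 of the day 3 controls were 0.936, 0.886, 0.893, 0.891, 0.888, 0.770 and 0.906. Those of the day 3 styrene group (replicates 1, 2, 3, 4, 5 and 7) were 0.818, 0.920, 0.866, 0.882, 0.921 and 0.868. The day 7 controls (replicates 2 to 7) had medians of 0.984, 0.927, 1.01, 0.902, 0.908 and 0.879, and the day 7 styrene group (replicates 1 to 6) 0.956, 1.01, 0.973, 0.849, 0.896 and 0.979.

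The main values were log2 of the processed signal minus log2 of the array's 75th percentile. Spots that the software marked as non-uniform or population outliers were left out (5450 of 339500 spots), saturated spots were kept (24 spots), and the remaining spots of a probe were averaged. A probe was above background on an array when most of its spots were marked well above background. Probes above background on at least 50% of the arrays of at least 1 group were tested, which left 2329. Leaving out population outliers as well as non-uniform spots was settled after a first fit that kept them had been seen. The smallest adjusted p at day 7 was 0.330 with these spots kept and 0.0774 without them, and neither fit called a probe. The group means were fitted to all 25 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3. There were 6 contrasts: styrene against control at each day, the difference of these effects between the days, their mean, and day 7 against day 3 in each treatment. A probe was called at a Benjamini-Hochberg adjusted p under 0.05. Every p-value of a single probe in the text is limma's. This test, the filter, the contrasts and the main alternatives were fixed before the data were examined.

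Every probe in the files carries only its own identifier, with the description "Unknown", and none of the 2716 has a gene name. The 26 gene lists fixed beforehand therefore had no testable member and were not run. Probes are reported by identifier and sequence. The rule for unnamed probes, fixed beforehand, allows at most 2 identifiers higher and 2 lower in exposed fish per styrene comparison, chosen by smallest p in each direction, and 1 probe so chosen is not reported here. For a probe that was not above background on any array of a group, a fold is given with that group's signals raised to a background floor. Per array, the higher of the probe's signal and the lowest signal among probes above background was used. The other group's signals were taken as measured, so the fold is a lower bound only where these are above background.

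The fit was tested on 20 simulated data sets for each day, made by shuffling the arrays' deviations over 2329 probes and changing 200 of them. The changes were 1.41-, 2-, 2.83- and 4-fold, in equal numbers within each data set. At day 3, 78.9% of probes changed by 2-fold were recovered, as were 36.7% of those changed by 1.41-fold and 96.2% of those changed by 4-fold. At day 7 the shares were 77.1%, 31.0% and 94.9%. False calls made up 4.9% and 2.9% of the calls. Because 200 probes changed together, the adjusted threshold was easier to pass than with few changed probes, where recovery would be lower.

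Sets of probes that vary together between livers were looked for after the data had been examined. Group means were removed, the 572 probes with a between-fish SD over 0.5 were clustered by average linkage on their correlation, clusters were joined down to a mean r of 0.5, and sets of at least 20 probes were kept. A set's score in a liver is the mean over its probes of the log2 level minus that probe's mean over all livers. Scores were compared between treatments by two-sided exact permutation tests at each day, 16 tests in all, with Benjamini-Hochberg adjustment. In 5 simulated data sets, the deviations of each probe were shuffled on their own and 1 shared factor was planted in 30 of 2298 probes. The search returned all 30 in 1 set and found no other set. Such shuffling removes any real correlation, so other sets could hardly arise. The planted factor varied more than the score of every set but the most variable, so the recovery of weaker sets was not checked. Whole profiles were compared by an exact permutation of the share of squared distance between treatments. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

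The 75th percentile signal ranged from 2359 to 6702 between arrays, and 73.4% to 86.8% of probes were above background. The median SD between spots of a probe on 1 array was 0.100 on the log2 scale, which gives an SE of 0.045 for a mean of 5 spots. The median SD of such means between fish of a group was 0.343. This SD also holds the noise of extraction, labelling and hybridization, since each fish had 1 array. The 25 arrays lay on 5 slides scanned on 1 day, and 4 of the slides held all 4 groups. Alternatives covered the background correction (normexp, offset 50), 3 other scalings, the series table, 2 filters on dim probes, slide as a fixed or random block, the replicate number as a block, the groups entering the fit, the variance model, array weights, spot medians and leaving out each array. Scan date could not serve as a block because there was only 1.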

Results

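Hepatic expression was profiled in 25 juvenile turbot to compare fish exposed to styrene in seawater with controls after 3 and 7 days. The groups were 7 controls and 6 exposed fish at day 3, and 6 controls and 6 exposed fish at day 7. Of 2716 probes, 1915 (70.5%) were above background on every array, and 302 were above background on none. Log2 levels are relative to the 75th percentile of the array. Arrays of the same group correlated at 0.945 to 0.989 across probes.

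After 3 days, no probe passed the test of exposed fish against controls. For 2024 of 2329 tested probes (86.9%) the 95% interval of the styrene effect lay within 2-fold in either direction. It lay within 1.5-fold for only 1338 probes (57.4%), so smaller changes remain possible at many probes. No probe was above background on all arrays of one treatment and on none of the other. Probe R1__1541 (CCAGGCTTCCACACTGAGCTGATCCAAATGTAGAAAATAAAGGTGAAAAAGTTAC) had a log2 level of -0.13 ± 0.22 (SD, n = 6) in exposed fish and -0.66 ± 0.31 (SD, n = 7) in controls. Probe R1__1881 (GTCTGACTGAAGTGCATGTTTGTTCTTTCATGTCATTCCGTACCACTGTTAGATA) had 1.32 ± 0.37 (SD, n = 6) in exposed fish and 2.19 ± 0.67 (SD, n = 7) in controls.

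These 2 probes differed by 0.53 (SE 0.15) and -0.87 (SE 0.26) on the log2 scale, both with a limma adjusted p of 0.998. The other probe of smallest p with a higher level in exposed fish was R1__1549 (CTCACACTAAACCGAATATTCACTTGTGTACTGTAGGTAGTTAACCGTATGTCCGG), at 0.41 (SE 0.12, adjusted p = 0.998), and the other with a lower level was R1__2161 (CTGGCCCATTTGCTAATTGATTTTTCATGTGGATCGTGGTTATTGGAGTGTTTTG), at -0.35 (SE 0.11, adjusted p = 0.998). On each of the 4 slides that held both groups, all 4 probes differed in the same direction as in the pooled data, R1__1541 by 0.37 to 1.25 and R1__1881 by -1.82 to -0.18. The probes were chosen for a small p on these same arrays, so this agreement is partly built in and is not independent support. With normexp background correction the difference of R1__2161 was 0.06. limma called 0 probes at an adjusted p under 0.05, and 69 had an unadjusted p under 0.05, where 116 would be expected by chance. Of the 69, 26 were higher and 43 lower in exposed fish, against 30 and 30 in the authors' series values and 31 and 29 with normexp background correction. With slide as a fixed block 125 probes had an unadjusted p under 0.05, without control day 3 replicate 4 the count was 41, and without control day 3 replicate 7 it was 109.

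After 7 days, more probes leaned away from the controls than at day 3, but again no probe passed the test. Probe R1__1254 (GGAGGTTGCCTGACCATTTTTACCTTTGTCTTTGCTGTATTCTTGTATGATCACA) was above background in 4 of 6 exposed fish and in 0 of 6 controls. With the control signals raised to the background floor, its mean in these exposed fish was 1.25-fold that in these controls, a ratio of sample means that carries no error. The exposed signals were taken as measured. Styrene day 7 replicates 2 and 6 were themselves below background, so 1.25-fold is not a strict lower bound. The lowest exposed fish, at -6.70, lay within the control range of -7.32 to -6.53. The measured log2 means of R1__1254 were -5.12 ± 1.03 (SD, n = 6) and -6.88 ± 0.27 (SD, n = 6).

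The difference of R1__1254 was 1.76 (SE 0.36), with a limma adjusted p of 0.0774, and both values rest on control signals at background. R1__2625 (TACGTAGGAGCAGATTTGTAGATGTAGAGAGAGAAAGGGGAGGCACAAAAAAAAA) differed by 0.75 (SE 0.22, adjusted p = 0.509) and R1__3477 (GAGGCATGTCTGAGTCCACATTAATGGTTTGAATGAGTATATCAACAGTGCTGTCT) by -0.45 (SE 0.12, adjusted p = 0.435). These 3 probes differed in the pooled direction on each of the 5 slides, R1__1254 by 0.86 to 2.98. They too were chosen on these same arrays, so the agreement is partly built in. limma called 0 probes, and 223 had an unadjusted p under 0.05, where 116 would be expected by chance. Of these, 70 were higher and 153 lower in exposed fish, against 105 and 120 after quantile normalization, 108 and 87 in the authors' series values and 84 and 81 with normexp background correction, so the lean towards lower levels depends on the processing. The 95% interval lay within 2-fold for 1908 probes (81.9%) and within 1.5-fold for 1092 (46.9%). Without styrene day 7 replicate 2, R1__1254 alone passed, at 2.08 (SE 0.32, adjusted p = 0.00335). That array is the lowest exposed fish, at -6.70 and within the control range, so leaving it out widens the difference by construction. With normexp background correction the difference of R1__1254 was 0.95. Without control day 7 replicate 7, 130 probes had an unadjusted p under 0.05.

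**Figure D1:**
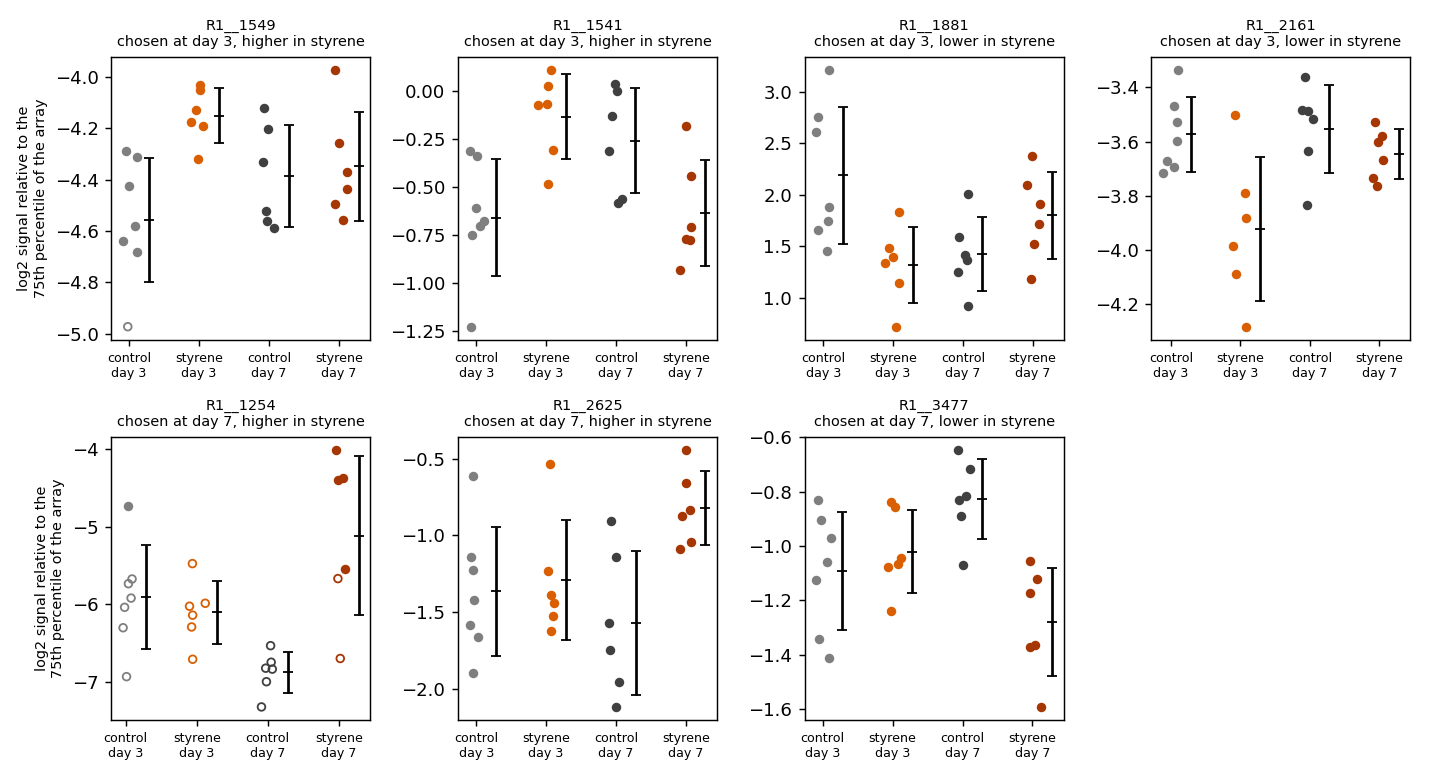
Log2 level, relative to the 75th percentile of the array, of 4 probes chosen at day 3 (top row) and 3 chosen at day 7 (bottom row) in each fish of the 4 groups. Filled points are above background and open points are not, and bars show the mean ± SD. R1__1254 is above background in 0 of 6 day 7 controls.

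The 2 time points were compared to see whether the response to styrene differed with the length of exposure. Of the probes above, R1__1541, R1__1881 and R1__3477 had effects of opposite sign on the other day. R1__1549 (0.04 at day 7, SE 0.12), R1__2161 (-0.09 at day 7, SE 0.11) and R1__2625 (0.07 at day 3, SE 0.21) kept their sign. Each probe was chosen for a small p on 1 day, so the choice alone favours a smaller or opposite effect on the other day. R1__1541 differed by 0.53 (SE 0.15) at day 3 and by -0.38 (SE 0.16) at day 7. R1__1881 differed by -0.87 (SE 0.26) at day 3 and by 0.38 (SE 0.27) at day 7. At day 3, R1__3477 differed by 0.07 (SE 0.11), and R1__1254 was above background in 1 of 7 controls and 0 of 6 exposed fish, so no day 3 effect or difference between days is given for it. The day 7 effect minus the day 3 effect was -0.90 (SE 0.22, adjusted p = 0.419) for R1__1541, 1.25 (SE 0.37, adjusted p = 0.435) for R1__1881 and -0.52 (SE 0.16, adjusted p = 0.435) for R1__3477. It was -0.37 (SE 0.17, adjusted p = 0.435) for R1__1549, 0.26 (SE 0.16, adjusted p = 0.54) for R1__2161 and 0.68 (SE 0.31, adjusted p = 0.435) for R1__2625. limma called 0 probes for this difference, with 262 at an unadjusted p under 0.05 against 116 expected, 105 of them with a higher effect at day 7 and 157 with a lower one. With normexp background correction the unadjusted count was 121, and without control day 3 replicate 7 the fit called 1 probe, R1__765 (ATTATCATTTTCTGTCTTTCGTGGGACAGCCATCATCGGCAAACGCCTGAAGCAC), at -1.06 (SE 0.20, adjusted p = 0.0390). R1__765 is outside the rule for named probes and was chosen after its values were seen. Across the 2329 probes, which are not independent replicates, the effects at day 3 and day 7 correlated at r = -0.361, and 16 of 100 groupings of the fish, the real one included, gave an r as far from 0.

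Averaged over both days, no probe passed the test. The 95% interval of the mean effect lay within 2-fold for 2201 probes (94.5%) and within 1.5-fold for 1809 (77.7%). limma called 0 probes, with a smallest adjusted p of 0.993, and 60 had an unadjusted p under 0.05 (15 higher and 45 lower in exposed fish, against 19 and 32 after median scaling and 31 and 22 in the authors' series values). This count was 142 with array weights. It was 117 with normexp background correction, with the direction turned (91 higher and 26 lower). It was 100 without styrene day 3 replicate 7 and 92 without styrene day 7 replicate 2.

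**Figure D2:**
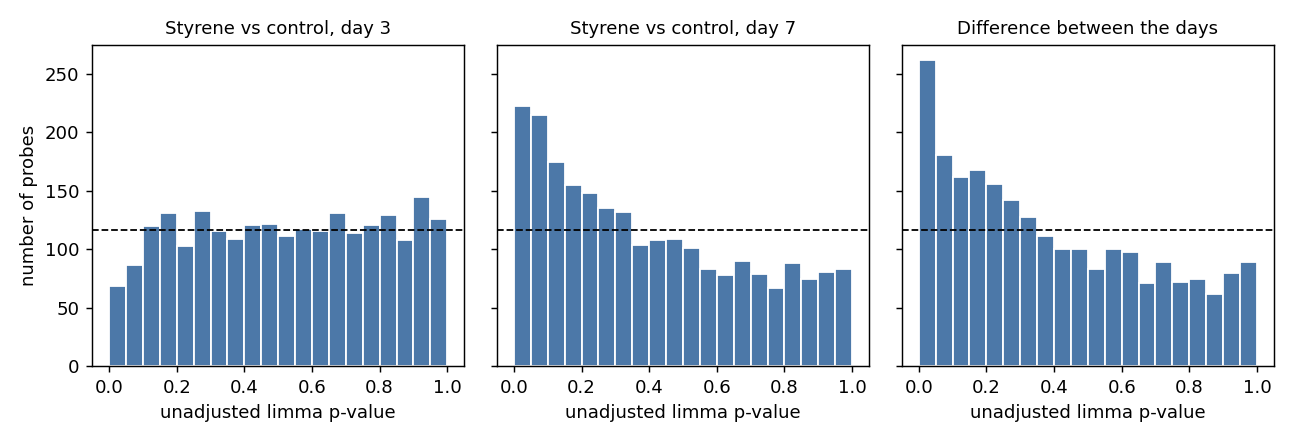
Number of probes by unadjusted limma p-value, in bins of 0.05, for styrene against control at day 3, at day 7 and for the difference between the days. The dashed line marks the 116 probes per bin expected with no effect, and the lowest bin holds 69, 223 and 262 probes.

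Day 7 was also compared with day 3 within each treatment. Among controls limma called 0 probes (smallest adjusted p = 0.381), and 174 had an unadjusted p under 0.05, 116 higher and 58 lower at day 7. The direction turned with the scaling: the split was 82 and 92 after median scaling, 74 and 93 after quantile normalization and 161 and 32 in the authors' series values. Among exposed fish limma called 0 probes (smallest adjusted p = 0.277), with 228 at an unadjusted p under 0.05, 86 higher and 142 lower at day 7. That split was 62 and 198 after median scaling and 173 and 62 in the authors' series values. With normexp background correction the 2 unadjusted counts were 78 (34 higher and 44 lower) and 101 (27 higher and 74 lower). Without control day 3 replicate 4 the count in controls was 91, and without styrene day 3 replicate 3 that in exposed fish was 149. Without control day 3 replicate 7, which enters this contrast only through the shared spread, the fit called R1__765 in exposed fish at -0.74 (SE 0.14, adjusted p = 0.0455).

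Livers of the same group differed widely at some probes. The median between-fish SD was 0.343 on the log2 scale, and 35 probes had an SD over 2. Of 8 sets of probes that varied together, defined after the data had been examined, the most variable held 31 probes, and its score spanned 9.64 on the log2 scale over the 25 livers. Only 5 of the 31 were above background on all arrays, so the low end of this span rests partly on signals at background, and over these 5 the span was 9.02. Its 31 probes made up 1.33% of the tested probes and 31.8% of the within-group variance, and took from 0.0127% to 6.98% of an array's summed signal. High and low livers occurred in every group: scores ran from -3.64 to 2.01 in day 3 controls, -4.69 to 2.71 in day 3 exposed fish, -3.28 to 3.99 in day 7 controls and -5.65 to 1.96 in day 7 exposed fish. The mean score was 0.50 higher in exposed fish at day 3 (two-sided exact permutation p = 0.716, adjusted p = 0.856; -0.06 to 1.47 with 1 array left out) and 1.29 lower at day 7 (a difference of -1.29, exact permutation p = 0.461, adjusted p = 0.856), or -0.27 without styrene day 7 replicate 1 and -2.09 without control day 7 replicate 7.

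In a second pattern, 53 probes (set 1) and 22 probes (set 6) moved in opposite directions from liver to liver. Their scores, with group means removed, correlated at r = -0.909 (permutation p = 1e-05, the smallest that the permutations can give) and rho = -0.896 (permutation p = 1e-05) over the 25 livers, among 28 relations between sets (adjusted p = 0.00028 for both). Without the 2 livers farthest from the median of set 1, r was -0.896. Another set of 20 probes (set 8) also went against set 6 (r = -0.567, permutation p = 0.0029, adjusted p = 0.041; rho = -0.673, permutation p = 0.00033, adjusted p = 0.0046; r = -0.532 without the 2 farthest). With set 1 it passed by rho alone (rho = 0.592, permutation p = 0.0023, adjusted p = 0.021; r = 0.497, permutation p = 0.011, adjusted p = 0.10; r = 0.469 without the 2 farthest). For sets 1 and 6, r within the 4 groups lay between -0.948 and -0.861, and within the 5 slides between -0.986 and -0.872. Sets 6 and 8 were less uniform, with r between -0.896 and -0.184 within the groups and between -0.964 and -0.191 within the slides. Neither set 1 nor set 6 passed the test between treatments: set 1 was higher in exposed fish by 0.12 at day 3 and by 0.40 at day 7 (exact permutation p = 0.794 and 0.348), and set 6 differed by -0.19 and -0.27 (exact permutation p = 0.538 and 0.446). With 1 array left out, set 1 ran from -0.05 to 0.32 at day 3 and from 0.23 to 0.60 at day 7, and set 6 from -0.33 to -0.04 and from -0.42 to -0.09. Over all 8 sets and both days, 0 of 16 exact permutation tests had an unadjusted p under 0.05, and 0 had an adjusted p under 0.05. Treatment accounted for 5.7% of the squared distance between whole profiles at day 3 (exact permutation p = 0.848) and for 10.0% at day 7 (exact permutation p = 0.307), where chance gives 8.3% and 9.1%.

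**Figure D3:**
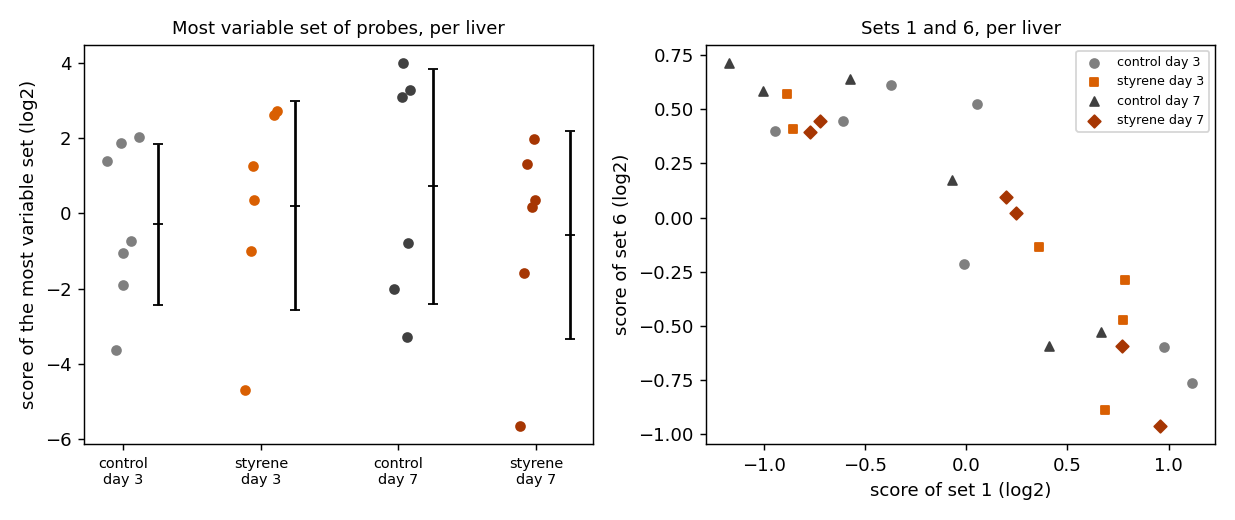
Left, score of the most variable set (31 probes, log2) in each liver by group, with bars for the mean ± SD. Right, scores of set 1 and set 6 (log2) in each of the 25 livers, which correlate at r = -0.909 with group means removed.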

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

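The comparisons with other groupings of the fish, the tests of the difference between days and the tests of the most variable set were chosen after the results were seen. Those of sets 1 and 6 were written down before their values were seen.

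The count of probes whose styrene effect leaned apart between days stood out in a test of the difference itself. Of 100 groupings with treatment shuffled within each day, 2, the real one included, gave as many as 262 probes at an unadjusted p under 0.05 (highest other 288). This share was under 0.05 with the main values, but not after correction over the 6 contrasts, and no single probe passed. From 100 groupings the share is known only roughly, so chance was not firmly excluded. With normexp background correction 29 of 100 groupings gave as many as the real 121 (highest other 476), so chance could not be excluded over all probes, and no set of probes differed between days (smallest permutation adjusted p = 0.428). In the brightest 777 probes, the share with such a p was 12.1% with the main values (94 probes, reached by 2 of 100 groupings). With normexp it was 9.40% (73 probes, reached by 5 of 100), and the spread between fish was 0.309 and 0.311. In the middle 776 normexp moved the share from 10.7% to 5.67% (spread 0.312 and 0.317), so the count there depended on the handling of background. In the dimmest 776 the share went from 11% to 0.515%, but the spread rose too (0.423 and 0.546). In the brightest probes the share fell only in part. The handling of background and a true effect therefore cannot be told apart in the brightest and the dimmest probes. The count of 340 with slide as a fixed block argues against slide as the whole cause, and a response that changes with the length of exposure, or a difference between the tanks over time, may contribute, neither of which was tested.

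For the other contrasts, day 7 exposed fish against day 3 exposed fish gave 228 such probes, reached by 4 of 100 groupings (highest other 302). This share was under 0.05 with the main values, but not after correction over the 6 contrasts. From 100 groupings it is known only roughly, so chance was not firmly excluded. With normexp the count was 101, reached by 50 of 100 groupings (highest other 945), so chance could not be excluded. For the remaining contrasts the share was over 0.05 with the main values, so chance could not be excluded there either. At day 3, 88 of 100 groupings reached the real count of 69, with a highest other count of 311. At day 7, 12 of 100 reached 223, with a highest other of 506. For the mean over both days, 78 of 100 reached 60, with a highest other of 529. For the days in controls, 17 of 100 reached 174, with a highest other of 369. At day 3 and over both days the highest other count was several times the real one, which may reflect a structure among the livers, but no test linked those groupings to one.

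The most variable set of 31 probes stood out by its range between livers of the same group. Slide accounted for 0.069 of the variance of its score, which argues against a slide effect. Of 465 pairs of its probes, 0 shared a run of 15 bases (0% of pairs), so its probes do not overlap in sequence. Probes at separate places of the same transcript would share no such run either, so this does not tell how many transcripts the set reads. RNA from one source, such as another tissue or cell type taken up in varying amount with the liver piece, is a candidate explanation: all members should then change by about the same log2 amount, and 77.4% of them had an SD of 0.8 to 1.25 times the median, below the 90% set for this explanation and above the 50% set against it. Of the 7 members under 0.8, 6 were not above background on all arrays, where the floor lowers the SD whatever the source. These 6 therefore cannot count against one source. Of the 5 members above background on all arrays, 4 lay within the bounds, and the floor does not account for the member outside them. Varying uptake of such RNA and joint regulation inside the liver therefore cannot be told apart. No gene name ties these probes to a cell type, and the probe sequences read under other observations do not decide it.

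The opposition of sets 1 and 6 was checked against 3 technical explanations. With slide as a fixed block r was -0.926, which argues against slide. After quantile normalization it was -0.920. A wrong scale factor for an array would move both scores in the same direction and could not make them oppose. The value after quantile normalization is therefore no test of array scaling. The difference of the 2 scores correlated at r = -0.144 (permutation p = 0.494) and rho = -0.188 (permutation p = 0.368) with the log2 75th percentile signal of the array, and at r = -0.217 without the 2 farthest livers, which argues against signal strength. A liver state that differs between fish and favours one set over the other may be present, as a hypothesis found and tested on the same data. The labels give no measure of the fish beyond treatment and day with which to test it.

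Single fish stood apart from their group in 7 of 76 sets of values, where chance gives about 3.8. Probe R1__2625 was at -0.53 in styrene day 3 replicate 4, with the nearest other fish at -1.23. The score of set 2 was -0.88 in styrene day 3 replicate 7, with the nearest other at -0.04, and that of set 3 was 2.22 in control day 7 replicate 7, with the nearest other at 0.72. The 75th percentile signal was 5846 in control day 7 replicate 4, above 4465 in the nearest, and 6702 in styrene day 7 replicate 3, above 4710 in the nearest. Control day 3 replicate 6 had 73.4% of probes above background, below 80.2% in the nearest array. The median spot SD was 0.079 in control day 7 replicate 4, below 0.105 in the nearest.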

How the results depend on the processing

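The alternatives for sets and whole profiles, the removal of the most variable set and the keeping of population-outlier spots were chosen after seeing the data. No alternative that kept all arrays called a probe at an adjusted p under 0.05 in any of the 6 contrasts. Over these, the smallest adjusted p ran from 0.342 to 1.0 at day 3 and from 0.0514 (array weights) to 0.566 at day 7, where it was 0.330 with population-outlier spots kept. Leaving out 1 array at a time gave 0 to 1 called probes at day 7, for the difference between days and between days in exposed fish, and 0 in the other contrasts. The unadjusted counts then ran from 41 to 109 at day 3, 130 to 308 at day 7, 186 to 328 for the difference, 41 to 100 over both days, from 91 to 1.41 times the full count between days in controls and 149 to 273 in exposed fish. Normexp moved the unadjusted counts to 121 for the difference, 117 over both days, 78 between days in controls and 101 in exposed fish. It also shifted the median styrene effect of all probes to 0.10 at day 3 and 0.12 at day 7. Slide as a fixed block moved the day 3 count to 125, and array weights moved that over both days to 142. The cause of these moves was not tested.

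R1__2161 turned to 0.058 with normexp, and the effect of R1__1254 at day 7 ran from 1.54 to 2.08 when 1 array was left out (adjusted p 0.00335 to 0.330). The 2.08 came from leaving out the lowest exposed fish of R1__1254. The other probes chosen by the rule and reported kept their direction in the alternatives that tested them, but R1__1254 was at 0.95 with normexp. Some set differences turned: with normexp set 2 at day 3 to 0.17, set 3 at day 7 to 0.023, set 5 at day 3 to 0.19 and set 7 at day 7 to 0.051, and over probes above background on all arrays set 1 at day 3 to -0.03 and set 7 at day 3 to -0.014. Leaving out 1 array gave ranges at day 3 of -0.047 to 0.321 for set 1, -0.287 to 0.031 for set 2, -0.11 to 0.26 for set 3, -0.061 to 1.474 for set 4, -0.340 to 0.054 for set 5 and -0.14 to 0.22 for set 7, and at day 7 of -2.087 to -0.273 for set 4 and -0.009 to 0.198 for set 5. No set passed an adjusted p of 0.05 in any alternative, nor when sets were joined at r = 0.4 (10 sets) or r = 0.6 (5 sets). Whole profiles stayed above an exact permutation p of 0.05 in all alternatives.

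Replicate numbers are shared between groups, but nothing in the labels pairs fish of separate tanks by them. Deviations of 33 same-numbered pairs correlated at -0.612 to 0.409, with a median of 0.106 (17 over 0.1) against -0.019 for other pairs (permutation p = 0.085), and 7 of 25 arrays correlated best with their own number, where shuffled numbers gave a median of 3 (permutation p = 0.0992), so a weak pairing is not excluded. With the replicate block, limma called 0 probes in each contrast, with unadjusted counts of 100 at day 3 and 215 at day 7, and set 5 at day 7 turned to -0.074. Gene lists were not run for want of gene names, nor was scan date, since 1 scan day covers all arrays. Dim probes, below background in part of the fish, are limited by signal over background.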

Other observations

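The reading of probe sequences described here was chosen after seeing the data, and the motifs were written down only after 2 of the probes had been read.

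The most variable set may hold RNA of exocrine pancreas, tissue that in many bony fishes lies within or around the liver, as a hypothesis. Of its 31 probes, 2 read in a forward frame as peptides that resemble digestive serine proteases. R1__836 (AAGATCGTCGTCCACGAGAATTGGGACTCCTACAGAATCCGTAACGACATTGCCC) reads as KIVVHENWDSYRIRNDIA, with the residues around the catalytic aspartate of that family, and R1__134 (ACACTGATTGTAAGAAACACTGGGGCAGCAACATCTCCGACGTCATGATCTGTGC) reads as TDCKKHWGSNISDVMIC. A search of all 3 forward frames with 4 motifs of the family found these 2 and 0 of the 2298 other tested probes. Because the motifs were shaped on these 2 probes, the count is not a test of enrichment and no p is given. The other 29 members matched none of the 4 motifs, which cover serine proteases only, so other pancreatic enzymes were not looked for. Most probes may lie outside coding sequence, and no reference sequence was at hand, so pancreatic RNA and other sources cannot be told apart.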
